A study of Mus musculus with 14 samples.

How the data were processed

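The data are 3P-seq libraries from mouse tissues, mESC and 3T3, made from total RNA per the labels' protocols. Wild-type and miR-22 knockout mice are given the background 129S5/SvEvBrd in the labels. Base calling used CASAVA 1.7 and alignment used Bowtie on build mm9, per the submitters' processing notes; the Bowtie version is not given in the sources used here. Each library has a list of poly(A) sites with an interval, a strand and a tag number. How reads were grouped into sites is not given in the sources used here. The values the authors deposited are estimated counts of tags per site that were not scaled. Between 1.21% and 5.79% of the sites of a library carry a value that is not a whole number, and the source of these fractions is not given in the sources used here. Neighbouring sites of a library and strand are at least 16 nt apart. Tissue libraries have intervals of up to 36 nt and the mESC and 3T3 libraries of up to 32 nt. The track lines of 13 of the files name mm9 and an offset of 1, which was not applied, so positions can differ by 1 nt from those a browser draws; the mESC list has no track line, and its build rests on the labels.

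Sites of the same strand whose intervals overlap or touch were merged over the 14 libraries, and their values were summed and rounded to whole numbers. The 3′ end of the most abundant interval gave the site's position. Abundance was analysed in R 4.3.3 with edgeR 4.0.16. Sites were kept by filterByExpr with tissue as the group and a minimum count of 10, libraries were scaled by TMM, and a quasi-likelihood model with a term for each tissue and 1 for genotype was fitted to the 12 tissue libraries. With 1 library per tissue and genotype, the 2 libraries of a tissue served as its replicates once genotype was a term, and the genotype effect was tested against its variation between tissues, with 5 residual degrees of freedom. The common biological coefficient of variation was 0.31. Each tissue was tested against the mean of the other 5, and a site was called at an adjusted p under 0.05 and a 4-fold difference. Genotype calls used an adjusted p under 0.05. Adjustment was by Benjamini-Hochberg over the 23856 sites tested. CPM values are TMM-scaled over tested sites. Tested sites held between 96.3% and 98.7% of a library's tags.

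Tandem pairs were taken as neighbouring tested sites on one strand 100 to 5000 nt apart. Each site had at least 5% of the pair's tags and the pair at least 20 tags in at least 6 tissue libraries. Of 8279 neighbouring pairs at that distance, 4248 passed. An edgeR model with a term for each library and distal-by-tissue and distal-by-genotype terms tested site use. Library size thus cancels, and so does transcript abundance where both sites end transcripts of the same gene. The median distal share per library was compared by exact permutation tests. These tests treat single libraries as exchangeable, although each tissue gave 2, so their p-values can be too small for differences between tissues. Within a tissue, sites at 20 CPM or more and 2-fold apart were counted, with exact binomial 95% intervals for the ratio of tags. Tags without molecular identifiers are not independent molecules, so these intervals, and the floor of 3 counts used where a group had 0 tags, cover counting error only.

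The sites named in the text follow a rule fixed before the data were examined, except the chromosome 11 site at 67010981, picked after the values were seen. Genotype tests are also printed for the chromosome 8 site at 85821894 and the chromosome 11 site at 32184325. The rule named both only within tissues. For tissues these are the 4 sites of largest fold difference with at least 50 CPM and both libraries above the other 10. For genotype they are up to 10 per direction of smallest p among those called and going the same way in 6 tissues. Within a tissue they are the 3 largest ratios per direction, for site use 3 pairs per tissue and up to 5 per direction for genotype, and for each cell line the 5 largest ratios at 50 CPM or more. Only some of the sites the rule gives are printed.

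The steps were tested on simulated counts drawn from the real library sizes and dispersions. For the genotype tests the means were the real ones of each tissue. For the tissue tests each site was given 1 mean level, and each pair 1 distal share, in all libraries before the change. Changed sites and pairs were drawn from those above a minimum mean number of tags, so recovery at sparser ones was not measured. With 200 of 23856 sites changed between genotypes, the genotype test recovered 5.5% of 2-fold, 80.5% of 4-fold and 96.5% of 8-fold changes. The tissue test recovered 100% of 200 sites raised 8-fold in 1 tissue. Among 4248 simulated pairs with 200 shifted, the genotype test of site use recovered 0.5% of 2-fold and 86.5% of 4-fold shifts in the odds of the distal site, and the tissue test 0% and 43%.

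Alternatives chosen before the data were examined were DESeq2 1.42.0 size factors and Wald test, no filter, sites joined over gaps of up to 24 nt, each library or pair left out, no tissue term, other minimum levels, total-count scaling and other rules for pairs. Alternatives chosen after seeing the data left out mitochondrial sites, chose pairs on the cell lines, or kept pairs with whole-number values or with at least 20 tags in all 14 libraries. Genome sequence and gene annotation of mm9 were not used here. The planned tests of sites carrying matches to the miR-22 seed or to other microRNA seeds, and the gene lists fixed beforehand, were therefore not analysed here, and no site is assigned to a gene, exon or UTR.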

Results

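Poly(A) sites, the positions at which transcripts are cleaved and given their poly(A) tail, were mapped by 3P-seq (poly(A)-position profiling by sequencing) in 14 mouse libraries. Heart, muscle, liver, lung, white adipose tissue and kidney were each represented by 1 wild-type and 1 miR-22 knockout library, 12 in all. The other 2 libraries came from mouse embryonic stem cells (mESC) and from 3T3, a mouse fibroblast line. The labels state that no group was replicated, and they do not say which tissues came from the same animal. The p-values given here therefore rest on the spread between libraries and between tissues, and not on the spread between animals of a group. The libraries held between 2036838 tags in knockout adipose tissue and 6010465 in knockout lung. The mESC library held 3672600 tags and the 3T3 library 4236185. Positions are given in mm9 and counted from 1. Gene names were not used here, since the annotation given belongs to another build, so each site is named by its chromosome and position. For the same reason the targeted miR-22 locus was not located here, and its level could not serve as a check on the genotype labels.

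The share of tags on the mitochondrial genome varied widely between tissues. It was 22.6% in wild-type and 31.3% in knockout heart, a mean of 26.9% ± 6.12 (SD, n = 2). Muscle held 21.3% ± 1.45 and kidney 19.6% ± 4.46, while liver held 5.58% ± 0.115 and lung 3.86% ± 0.487 (SD, n = 2 each). In heart the exact two-sided permutation p over 66 splits was 0.0303, or 0.182 after Benjamini-Hochberg adjustment over 6 tissues. The splits treat single libraries as exchangeable, although each tissue gave 2, so this p can be too small for a difference between tissues. A small number of sites carried most transcripts in muscle, where 13 sites held 50% of the wild-type tags and 16 sites held 50% of the knockout tags. The corresponding numbers were 33 and 38 in heart, 149 and 167 in liver, 548 and 707 in lung, 107 and 144 in adipose tissue, and 208 and 297 in kidney. These numbers depend on the mitochondrial share: among nuclear tags they were 75 and 171 in heart, 31 and 34 in muscle, and 493 and 511 in kidney. Over all tags the number was higher in the knockout library of 6 of 6 tissues, by 0.33 ± 0.134 on the log2 scale (SD, n = 6). Its exact sign-flip p was 0.0312, the smallest this design allows, and 0.125 after adjustment over 4 library measures.

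Merging the sites of all libraries gave 159969 sites. Of these, 14374 carried tags in all 14 libraries and held 74.6% of all tags. A further 31896 sites, 19.9% of the total, were seen in 1 library only and held 0.158% of the tags. Counting a site in a library only when it held at least 1e-06 of the library's tags left 8001 sites in all 14 libraries and 19680 in 1 only. Across sites, the Spearman correlation between the wild-type and knockout libraries of a tissue was 0.952 in liver, 0.949 in lung, 0.935 in muscle, 0.934 in kidney, 0.928 in heart and 0.91 in adipose tissue. Between different tissues it lay between 0.441 and 0.775, so that each library was closest to the other genotype of its own tissue. Heart and muscle were the nearest pair of tissues, at a mean of 0.766, and muscle and liver the most distant, at 0.444. Liver was closest to kidney, at 0.665. These correlations are across the 23856 tested sites, which are not independent replicates. The filter on the tissue libraries also kept sites abundant in 1 tissue alone. Such sites can raise the correlation within a tissue above that between tissues.

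Each tissue was compared with the mean of the other 5 to ask how far poly(A) site abundance differs between cellular contexts. Liver had 3302 sites higher and 2356 lower, kidney 3282 higher and 971 lower, and lung 2988 higher and 1123 lower. Heart had 2182 higher and 711 lower, muscle 2053 higher and 1637 lower, and adipose tissue 2063 higher and 809 lower. These calls are out of 23856 tested sites, at an edgeR quasi-likelihood adjusted p under 0.05 and at least a 4-fold difference. The order of tissues depends on these limits: at the edgeR adjusted p alone lung had the most sites higher, 6308 against 5387 in liver and 5308 in kidney. With no filter on low counts lung again had the most, 8161 against 6600 and 5754. The sites called higher held 58.4% of the tags of muscle libraries, 58.2% in liver and 57.5% in heart, but 40.4% in adipose tissue, 33.7% in lung and 29.9% in kidney (means of 2 libraries). The count of sites lower in muscle was the one that rested on a single library: it was 860 without the wild-type muscle library.

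The most abundant of the sites that set a tissue apart was in muscle, at chromosome 11, 67073849 to 67074018 (+). It reached 108400 ± 4169 CPM (counts scaled to a common library size; SD, n = 2), against at most 347 CPM in the other 10 libraries. A second muscle site, at chromosome 7, 149701734 to 149701914 (+), reached 39520 ± 626 CPM, against at most 110.3 CPM elsewhere. In heart, 2 of the 4 leading sites were near each other on chromosome 10. The site at 53063972 to 53064145 (+) had 8811 ± 3933 CPM in heart and at most 59.4 CPM elsewhere. The site at 53065340 to 53065388 (+) had 621 ± 172 CPM, against at most 3.24 CPM. In liver the site at chromosome 1, 173156278 to 173156516 (+) had 14610 ± 3777 CPM against at most 91.2 CPM, and the site at chromosome 3, 82846151 to 82846523 (-) had 11430 ± 472 CPM against at most 61.5 CPM. In kidney the site at chromosome 7, 126606209 to 126606411 (-) had 1521 ± 367 CPM against at most 13.7 CPM. The lower of the tissue's 2 libraries exceeded the highest other library by between 102-fold and 354-fold at the 4 leading sites of heart, muscle and liver. The margin was between 25.3-fold and 92-fold in kidney. It was between 24.6-fold and 54.4-fold in adipose tissue and between 10.8-fold and 28.5-fold in lung. In lung the site at chromosome 19, 9158111 to 9158301 (-) had 6325 ± 3280 CPM, yet another library reached 370 CPM. In adipose tissue the site at chromosome 10, 79355232 to 79355418 (+) had 31400 ± 10750 CPM and another library reached 968 CPM. Every site printed here had an edgeR adjusted p of 2.54e-31 or less.

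**Figure D1:**
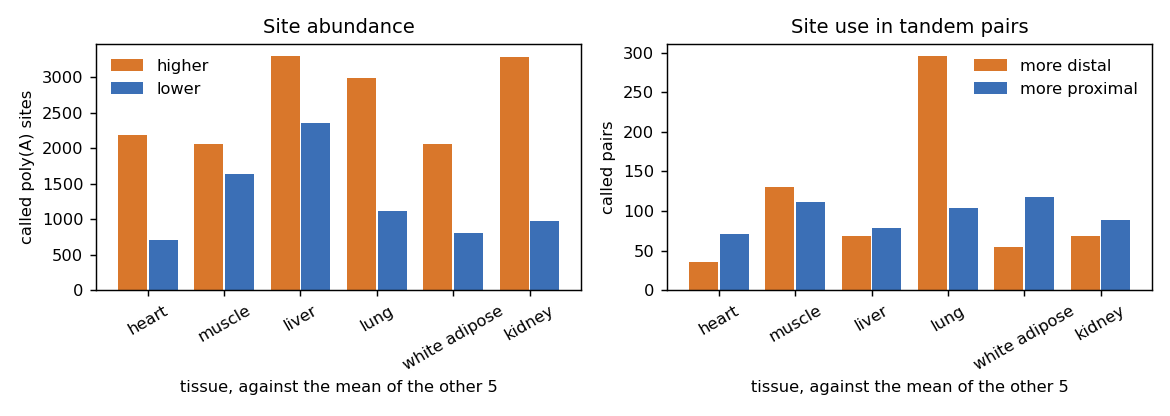
Bars give the number of poly(A) sites called higher or lower in abundance (left) and of tandem site pairs called more distal or more proximal (right) in each tissue against the mean of the other 5. With the low-count filter and the 4-fold limit liver and kidney had the most sites called higher, 3302 and 3282, and lung had the most pairs called more distal, 296.

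The genotype comparison asked which sites differed between miR-22 knockout and wild type in the same way across tissues. The clearest difference was a site at chromosome 1, 162968610 to 162968688 (+). It carried 19 tags over the 6 wild-type libraries and 2491 over the 6 knockout libraries, or 1.07 ± 0.99 and 92.7 ± 40.3 CPM (SD, n = 6 tissues). Its fitted log2 difference was 6.63 with a standard error of 0.427 (edgeR adjusted p = 2.18e-18), and it was higher in knockout in 6 of 6 tissues. A smaller site on the same strand, at 162966818 to 162966875, had 4 wild-type and 53 knockout tags. The site of second smallest p, at chromosome 8, 85821894 to 85821981 (+), was higher in knockout in 5 of 6 tissues (log2 difference 4.47, edgeR adjusted p = 1.81e-09). Most of its tags were in adipose tissue. It had 1.36 and 58.8 CPM in wild-type and knockout muscle and 0.442 and 10.6 CPM in lung, tissues in which sites that set adipose tissue apart also had higher medians in knockout (log2 0.26 and 0.46). In kidney, where that median was -0.01, the site had 0 and 3.78 CPM. Among sites that rose in 6 of 6 tissues, the next by p were a pair 4 kb apart on chromosome 11. The site at 75284315 to 75284416 (+) rose from 40.8 ± 52.2 to 204.4 ± 133.6 CPM, a log2 difference of 2.69 with a standard error of 0.385 (edgeR adjusted p = 1.39e-05). The site at 75280118 to 75280192 (+) rose from 20.1 ± 12.3 to 98.4 ± 64.1 CPM, a log2 difference of 2.07 with a standard error of 0.34 (edgeR adjusted p = 0.00033). At the first of these the within-tissue log2 difference ran from 0.59 in liver to 5.91 in muscle, so its size was far from even between tissues.

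Sites lower in knockout were fewer. The site at chromosome 11, 32197145 to 32197193 (+) fell from 27 ± 34.5 to 5.35 ± 5.26 CPM (log2 difference -2.04, edgeR adjusted p = 0.00122). The site at chromosome 7, 110961034 to 110961181 (-) fell from 46.5 ± 39 to 17.3 ± 21.3 CPM (log2 difference -1.62, edgeR adjusted p = 0.00402). Both were lower in 6 of 6 tissues, but the call at the chromosome 7 site was lost without the kidney pair (edgeR adjusted p = 0.101). Each had a neighbour on its strand that was also called lower. These lay at chromosome 11, 32184325 to 32184365 (log2 difference -1.92, edgeR adjusted p = 0.00402) and chromosome 7, 110975047 to 110975226 (-1.4, 0.025). The first neighbour was lower in 5 of 6 tissues and the second in 6. Such neighbouring calls need not be separate differences. The site of smallest p, at chromosome 1, 154365670 to 154365719 (-), was sparse, with 69 wild-type and 2 knockout tags in total (edgeR adjusted p = 1.25e-05).

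In all, 66 sites were higher and 16 lower in knockout out of 23856 tested. Of these, 29 and 5 went the same way in 6 of 6 tissues, and 1663 sites had an unadjusted p under 0.05. The number depended on which tissues were included: without the heart pair it was 38 higher and 9 lower, without the kidney pair 30 and 10, without the lung pair 123 higher, and without the adipose pair 42 lower. DESeq2 called 36 higher and 25 lower, and 1 site was called with no term for tissue. Among the 32 ways of swapping genotype labels within tissues the real one gave the most calls, 82, but swapping muscle and lung gave 77.

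**Figure D2:**
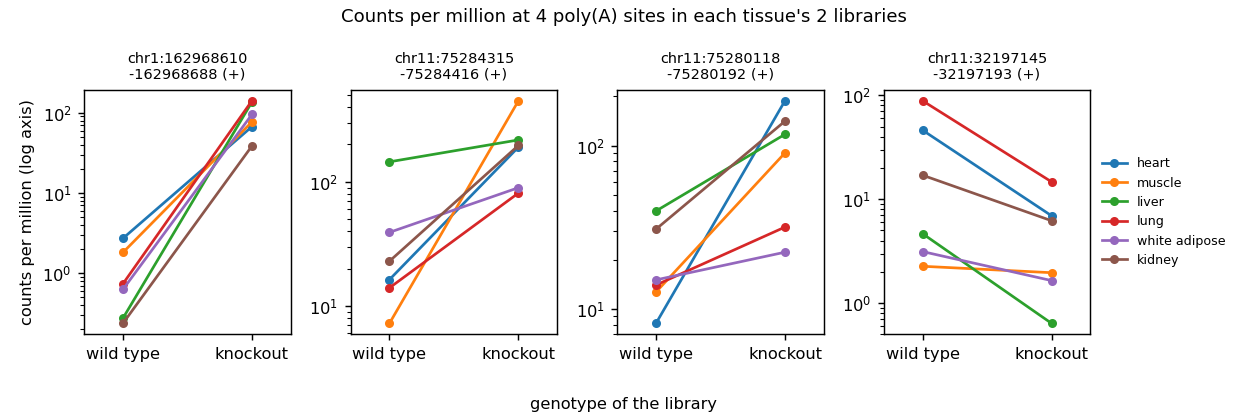
CPM (log axis) at 4 of the sites called between genotypes, with a line joining the wild-type and knockout library of each tissue. The chromosome 1 site lay at or below 2.72 CPM in the wild-type libraries and at or above 38.6 CPM in the knockout libraries; the chromosome 11 site at 32197145 fell in 6 of 6 tissues.

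**Figure D3:**
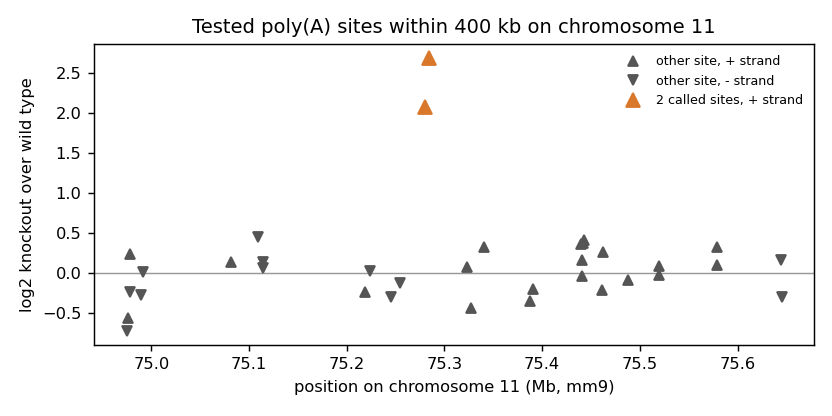
Fitted log2 difference between knockout and wild type (vertical axis) of each tested site within 400 kb, by position on chromosome 11 (Mb, mm9). The 2 called sites, at 2.07 and 2.69, stand above the other 33 sites, whose median was 0.02.

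Within a tissue, 1 library was compared with 1, so no test was made and the ratios carry counting error only (exact binomial 95% intervals). Adipose tissue had the largest share of sites that differed at least 2-fold, 35.2% of 4462 sites with at least 20 CPM. The share was 25.2% in heart, 21.2% in muscle, 19.7% in kidney, 13.3% in lung and 10.9% in liver. These shares and their order hold for TMM scaling. The chromosome 1 site at 162968610 was among the 3 largest increases in every tissue, from 24.8-fold in heart (11.2 to 68.3) to 192-fold in lung (82.2 to 593). In liver, where wild type had 1 tag, the ratio was 497 (88.8 to 19700). Other large differences were less even between tissues. In knockout adipose tissue the chromosome 8 site at 85821894 was 18.7-fold higher (15.3 to 22.9), at 631 against 33.8 CPM, and in muscle it was 43.3-fold higher (14.4 to 214), while heart had 0.453 and 0.66 CPM and liver 0. In knockout lung the site at chromosome 5, 91190616 to 91190659 (+) was 67.7-fold lower (40 to 124), at 1.45 against 98.1 CPM. In knockout muscle the site at chromosome 10, 80661937 to 80662001 (-) was 16.7-fold lower (13.5 to 20.9), at 57.5 against 959 CPM.

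Both the number and the direction of these single-library differences depended on the scaling. Scaling by total counts took muscle from 926 to 519 sites and lung from 701 to 1165, so that lung then had more than muscle. With TMM scaling, 45.4% of the 2-fold differences in heart were higher in knockout (518 higher, 623 lower). Scaling by total counts shifted every log2 ratio by 0.33 in heart and gave 76.6% (741 and 226). The share moved from 28.1% to 49.3% in muscle (260 and 666, then 256 and 263), and from 45% to 59.3% in liver. It moved from 59.1% to 74.1% in lung, and from 35.4% to 66.8% in kidney (342 and 623, then 714 and 355). In adipose tissue it moved from 40.4% to 49.7% (635 and 935, then 858 and 868). The shifts were 0.28 in muscle, 0.11 in liver, 0.12 in lung, 0.10 in adipose tissue and 0.23 in kidney.

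Sites that set 1 tissue apart also differed between the genotypes of another tissue. The lists used here hold the sites called higher in a tissue at 50 CPM or more with both of its libraries above the other 10; they were drawn up after the data were seen. Of 275 adipose sites with at least 10 tags in the lung libraries, 205 were higher in knockout lung, with a median log2 ratio of 0.46. That median lay above all 10000 random lists matched on abundance. In muscle 164 of 255 adipose sites were higher in knockout, with a median of 0.26, again above all 10000 random lists. In adipose tissue 174 of 262 kidney sites were lower in knockout, with a median of -0.48, below all 10000 lists. These are the 3 of 30 combinations whose median lay farthest from that of their random lists. In all, 7 combinations lay above and 7 below the middle 95% of their random lists. The values are for TMM scaling. With total counts the 3 medians were 0.59, 0.53 and -0.37, but the direction of many others turned round, among them muscle sites in heart (-0.27, then 0.05). Total-count scaling moves all ratios of a tissue by nearly the same amount, so a list and its random lists move together. Such turns follow from the scaling and hardly change where a list lies among its random lists. An adipose site at chromosome 7, 86865109 to 86865193 (-), among the 4 leading adipose sites, had 2.8 CPM in the wild-type and 48.4 CPM in the knockout lung library. These percentiles describe the libraries and do not test the genotypes.

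**Figure D4:**
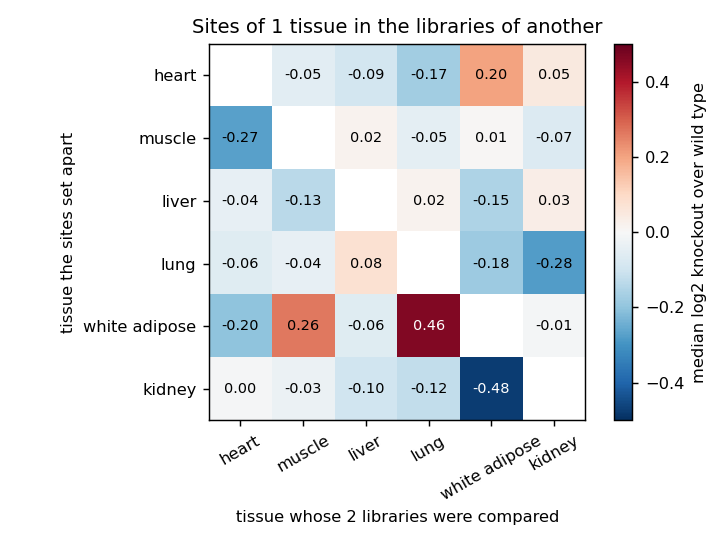
Each cell gives the median log2 ratio of knockout over wild type, in the tissue of the column, of the sites that set the tissue of the row apart; red is higher in knockout and blue lower, with TMM scaling. Adipose sites in lung (0.46) and kidney sites in adipose tissue (-0.48) lie farthest from 0.

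Site use was compared in 4248 tandem pairs, neighbouring sites on one strand a median of 709 nt apart, to ask whether transcripts of a tissue end at the proximal or the distal site. Lung stood out with 296 pairs shifted toward the distal site and 104 toward the proximal site. Adipose tissue had 55 more distal and 118 more proximal. Heart had 36 and 71, muscle 130 and 111, liver 69 and 79, and kidney 69 and 89 (edgeR adjusted p under 0.05), and 864 pairs were called in at least 1 tissue. Coverage was unequal: 4135 and 4207 pairs had at least 20 tags in the wild-type and knockout lung libraries, against 2970 and 2391 in muscle. The numbers of called pairs therefore also depend on how well a tissue was covered. These counts rested on both libraries of a tissue: without the wild-type muscle library muscle had 8 more distal and 9 more proximal pairs, and without the knockout adipose library adipose tissue had 8 and 6. Without the wild-type adipose library it had 33 and 19, so its lean toward proximal sites turned round without either of its libraries. The same held in kidney, with 16 and 8 without wild type and 13 and 12 without knockout. Without the wild-type lung library lung had 120 and 53.

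The pair at chromosome 11 with its proximal site at 120590804 and its distal site at 120586737 (-) separated liver and kidney from lung. In liver 99.9% ± 0.071 of its tags lay at the distal site, against 35.8% ± 37.8 in the other 10 libraries (SD; edgeR log2 shift 11.14), but those others include kidney at 99.1% and 98.6%. In lung the share was 4.85% ± 1.97, against 54.9% ± 41.5 (log2 shift -6.59). The pair held 994 and 716 tags in the wild-type and knockout liver libraries, but 43983 and 62797 in those of lung. The low share in lung thus goes with many more tags at the proximal site and need not mean fewer at the distal site. The pair on chromosome 17 at 34734346 and 34737876 (+) was 90.7% ± 4.62 distal in lung and 11.1% ± 23.5 distal elsewhere, where heart had 66.7% and 41.7%. In heart the pair on chromosome 9 at 66364038 and 66359411 (-) was 96.2% ± 0.0093 distal, against 9.93% ± 9.85. Heart and muscle shared a shift toward the proximal site of the pair on chromosome 3 at 122813882 and 122809520 (-), with 1.69% ± 1.53 and 0.979% ± 0.223 at the distal site. In kidney the pair on chromosome 7 at 51723125 and 51727020 (+) was 10.6% ± 1.23 distal, against 79.6% ± 38.8 elsewhere among 10 libraries that include liver at 6.34% and 5.97%. The edgeR adjusted p of these pairs was 8.53e-05 or less. These neighbouring sites were not tied to a gene here, and sites several kb apart need not end the same gene.

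Between genotypes 1 pair passed the threshold. It lay on chromosome 1 at 162966262 and 162966869 (+), about 1.8 kb from the site with the largest abundance difference, and shifted toward the distal site in knockout (edgeR log2 shift 4.01, adjusted p = 0.00251). Its distal site is the smaller chromosome 1 site that rose in abundance, so this is not separate evidence, and the pair held at most 63 tags in a library. Its distal share rose from 0% to 25.4% in lung, from 3.03% to 32% in liver and from 2.7% to 35.7% in kidney. No pair shifted toward the proximal site, and 287 pairs had an unadjusted p under 0.05 in edgeR. The call was lost without the liver pair (edgeR adjusted p = 0.053), without the kidney pair (0.0649), and among pairs with at least 50 tags in 6 libraries, where 0 pairs were called. The size of the log2 shift changed little, to 4.115 without the liver libraries and 3.953 without the kidney libraries.

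The median distal share over pairs also put lung and adipose tissue at opposite ends. It was 56% in both lung libraries and 48.9% and 50% in the adipose libraries, and lay between 50% and 52.9% in the other 8. Lung was 4.5 points above the other 10 libraries. Its exact two-sided permutation p of 0.0152 is the smallest that 66 splits allow, and it was 0.0912 after Benjamini-Hochberg adjustment over 6 tissues. Adipose tissue was lower by 3.41 points (exact permutation p = 0.0455, adjusted 0.136). The other 4 tissues differed by 1.42 points or less, with exact permutation p between 0.47 and 0.742. All these permutation p-values treat single libraries as exchangeable, yet the 2 libraries of a tissue were close (SD 0.032 points in lung). Those of lung and adipose tissue are therefore too small as tests of 1 tissue against the others. The knockout library was higher in 5 of 6 tissues, by 0.762 ± 0.84 points (SD, n = 6; exact sign-flip p = 0.0938). That difference was -0.146 points over the 1386 pairs with at least 20 tags in all 14 libraries.

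**Figure D5:**
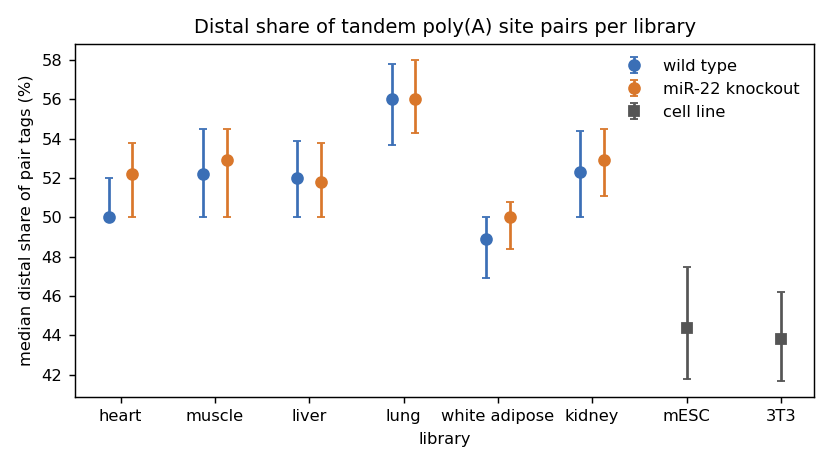
Median share of a tandem pair's tags at its distal site (vertical axis, percent) in each library, with 95% bootstrap intervals over pairs. The 12 tissue libraries lie between 48.9% and 56%, above mESC at 44.4% and 3T3 at 43.8%.

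The mESC and 3T3 libraries, 1 each, were set beside the tissues as values without a test. Across the tested sites they resembled each other (Spearman correlation 0.803) more than they resembled the tissues, with means of 0.547 and 0.563. Those sites were chosen on the tissue libraries alone, so sites low in both lines can raise the correlation between the lines. Both also had intervals of up to 32 nt, against 36 nt in the tissue libraries. Here and in the counts below a batch cannot be told apart from the kind of sample. Of 2832 sites with at least 50 CPM in mESC, 1750 were at least 4-fold above the mean of the tissue libraries. In 3T3 these were 1335 of 2644. Of 2548 sites with at least 50 CPM in the tissue mean, 1479 lay at or below 0.25 of that mean in mESC and 1306 in 3T3. In mESC the site at chromosome 4, 98405136 to 98405169 (+) had 5833 tags, 1562 CPM, while the 12 tissue libraries together had 7. The site at chromosome 6, 70912654 to 70912682 (+) had 3785 tags in mESC and 0 in the tissues and in 3T3. Set against 3 counts over the 12 libraries, it was at least 15300-fold higher. In 3T3 the site at chromosome 1, 40504937 to 40505005 (+) had 12361 tags, 2957 CPM, and 7 tags in the tissues. The site at chromosome 10, 103029366 to 103029394 (+) had 432 tags in 3T3 and 0 in the tissues, at least 1560-fold higher.

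Both lines used proximal sites more. Their median distal shares of 44.4% and 43.8% lay below the 12 tissue libraries, whose mean was 52.3% ± 2.16 (SD). The differences of -7.83 and -8.52 points shrank to -4.43 and -5.04 points with means over pairs. Of 1427 pairs with at least 20 tags in mESC and in each tissue library, 38.5% had a distal share below all 12 tissue libraries and 25.6% above all 12. In 3T3 these were 33.7% and 21% of 1535 pairs. Chance alone places 7.69% on each side if the 12 libraries are independent, and up to 14.3% if the 2 libraries of a tissue count as 1. Over the 63 pairs with whole-number values in mESC, 34.9% lay below and 12.7% above, so the share above is not clear of chance there.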

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

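None of 20 sets of 6 within-tissue genotype differences passed the critical value of Dixon's test. The sets were the named genotype sites and library measures, among them the mitochondrial share and the distal share. The named sites had been picked for going the same way in 6 of 6 tissues. Calls resting on 1 tissue were thus largely left out beforehand. The called site at chromosome 11, 67010981 to 67011013 (+), left out in this way, had a log2 difference of 4.94 in muscle and between -0.08 and 0.48 elsewhere. The 3 patterns weighed here were picked after their values were seen. The tests of the pairs' origin and of shared reads in the cell lines, and the label swaps, were set before their results; the tests of the 2 genotype patterns and of interval length were chosen after.

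The lower distal share of mESC and 3T3 was weighed against the way pairs were chosen. With 3004 pairs chosen on the mESC and 3T3 libraries themselves, the higher of their 2 medians stayed -3.77 points from the lowest tissue library (95% bootstrap interval -5.69 to -1.37), which argues against the choice of pairs as the whole cause. Reads shared between places in the genome stay open. Over 817 pairs with whole-number values in all 14 libraries the difference was -4.55 points, but its interval of -7.14 to 1.33 includes 0. These pairs were sparse: 63 of them had at least 20 tags in mESC and in each tissue library, against 1427 of all 4248 pairs. The source of fractions is not given either, so this comparison does not isolate shared reads. The widest interval of the cell-line libraries differed from that of the tissues by -4 nt, so a batch with shorter reads cannot be told apart from the kind of sample. A difference between cultured cells and tissues remains an untested biological explanation.

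The 2 chromosome 11 sites at 75280118 and 75284315 that rose in knockout were weighed against a change of a wider stretch of the chromosome. The median log2 difference of the other 33 tested sites within 400 kb was 0.0181 (95% bootstrap interval -0.136 to 0.127), which argues against such a change. Fractional values stood in 9 of the 24 values of these sites. Their source is not given, and fractions were common: 817 of 4248 tandem pairs had whole-number values in all 14 libraries. These fractions therefore cannot decide on reads shared with other places in the genome, which remain open. An effect of the genotype on the transcripts that end there is an untested biological explanation, since the sites were not tied to a gene. The median within 400 kb speaks to a wider stretch and not to a change confined to the surroundings of these 2 sites. The targeted miR-22 locus was not located here, so the distance of the sites from it was not determined.

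The chromosome 1 site at 162968610, nearly without tags in wild type, was weighed in the same way. The other 23 tested sites within 400 kb had a median log2 difference of 0.15 (95% bootstrap interval -0.281 to 0.315), which argues against a change of the wider region. Fractional values stood in 3 of 12 libraries. As their source is not given and fractions were common among tested sites, they cannot decide on shared reads, which remain open. Genotype, and any other sequence difference between the wild-type and knockout animals, remain untested as biological explanations.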

How the results depend on the processing

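Apart from values with a library left out, 165 of 224 recomputed counts and shares kept their direction and their side of the threshold or stayed within 1.5 times, and 358 of 402 did so with a library or pair left out. Among single named sites, 562 recomputed values kept their call and 23 lost it, none with a change of sign; 14 of the 23 were lost with no tissue term. For named pairs 336 of 352 kept their side. The planned tests with microRNA seeds were not run. Except where stated, the cause was not tested. Alternatives without mitochondrial sites, with pairs chosen on the cell lines, with whole-number values or with at least 20 tags in all 14 libraries, and leaving a library out of the distal shares, were chosen after seeing the data.

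With no filter on low counts more sites were tested, and sites higher numbered 4111 in heart, 3400 in muscle, 6600 in liver, 8161 in lung, 3436 in adipose tissue and 5754 in kidney, with 706 lower in lung. DESeq2's Wald test gave 1714 lower in lung, and 36 higher and 25 lower in knockout, where 24 of the 82 main calls had no adjusted p and 36 were called again. With no tissue term, 1 site was higher and 0 lower in knockout. Leaving out a library, sites lower in muscle ranged from 860 to 1646. Leaving out a tissue's pair, sites higher in knockout ranged from 30 to 123 and lower from 9 to 42.

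Within tissues, fewer sites pass a higher minimum. At 50 CPM the sites 2-fold apart numbered 576 in heart, 475 in muscle, 209 in liver, 261 in lung, 773 in adipose tissue and 411 in kidney. At 10 CPM they numbered 1751, 1409, 977, 1267, 2389 and 1557. Scaling by total counts gave 519 in muscle and 1165 in lung.

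For site use, pairs 300 to 3000 nt apart are fewer, 2751, and gave (more distal, then more proximal) 18 and 47 in heart, 86 and 71 in muscle, 37 and 45 in liver, 191 and 51 in lung, 30 and 72 in adipose tissue, and 34 and 46 in kidney. Requiring 50 tags left 2163 pairs, with 47 more proximal in heart, 37 more distal in liver, 40 more distal and 49 more proximal in kidney, and 0 shifted between genotypes. Leaving out a library, more distal pairs ranged from 11 to 46 in heart, 8 to 160 in muscle, 14 to 90 in liver, 120 to 312 in lung, 8 to 74 in adipose tissue and 13 to 102 in kidney. More proximal pairs ranged from 11 to 89, 9 to 139, 16 to 101, 53 to 105, 6 to 180 and 8 to 123. The lowest value came from leaving out one of the tissue's own libraries, where the lone library is assumed to vary like the others. Leaving out a pair, the genotype calls ranged from 0 to 2.

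For the overall distal share, the difference between genotypes gave exact p = 0.0312 with pairs 300 to 3000 nt apart (0.768 points) and with means (0.353 points), but was -0.146 points over pairs with at least 20 tags in all 14 libraries; exact p over its settings ranged from 0.0312 to 0.938. Small tissue differences changed sign: muscle was -0.529 points with each site at least 10% of the pair and between -0.0025 and 0.796 with a library left out. Kidney was -0.221 with 50 tags and -0.198 with means, and liver 0.0953 with means. With means mESC lay -4.43 points and 3T3 -5.04 points from the tissue mean. Over the few pairs with whole-number values, 63 in mESC and 78 in 3T3, 34.9% lay below and 12.7% above all 12 tissue libraries in mESC, and 29.5% and 17.9% in 3T3. With pairs chosen on the cell lines 19% lay above in 3T3. Counting only sites with at least 1e-06 of a library's tags leaves out rare sites: 8001 were in all 14 libraries and 19680 in 1 only.

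In simulated data 5.5% of 2-fold genotype changes were recovered, so small changes would be missed.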

Other observations

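Called sites were spread unevenly over the chromosomes in some tissues. On the mitochondrial genome 22 of 49 tested sites were higher in heart (odds ratio 8.16, adjusted Fisher's exact p = 7.27e-09) and 20 of 49 in kidney (odds ratio 4.34, adjusted Fisher's exact p = 0.000124), while 0 of 49 were higher in liver and in lung. On chromosome 11, 9.22% of tested sites were higher in liver, against 13.8% of all sites (odds ratio 0.612, adjusted Fisher's exact p = 1.73e-08). Chromosome 19 went the other way in liver, with 18.7%. These p-values treat sites as independent, and neighbouring sites are not.

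Chromosome Y held between 158 and 1255 tags in the tissue libraries and 3081 in mESC. The 3T3 library, of similar depth, had 7 tags there.

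Whether other groupings of the libraries give as many genotype calls was examined over the 32 ways of swapping the genotype labels within tissues. For site abundance only 1, the real one, gave 82 sites or more; the highest other gave 77, with the muscle and lung labels swapped. For site use 5 of the 32 gave 1 pair or more, the highest other being 3, so chance cannot be excluded there.

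The tests below were chosen after the values were seen. A first hypothesis held that the genotype calls gather on chromosome 1 or 11. Chromosomes 1 and 11 each held 11 of the 82 calls, with odds ratios of 2.3 and 1.82. The smaller adjusted Fisher's exact p of the pair was 0.411, which leaves gathering open. A second hypothesis held that knockout changed the same sites alike in several tissues. Over 2277 abundant nuclear sites the 15 correlations of knockout over wild-type ratios between tissues had a median of 0.0439. They ranged from -0.35 between heart and adipose tissue to 0.379 between adipose tissue and kidney. The correlations run both ways, and each ratio sets 1 library against 1 with no measure of noise, so these values leave a shared response open.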
